A study of Homo sapiens with 12 samples.

How the data were processed

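RNA recovered by immunoprecipitation from RKO cells, an established human colorectal carcinoma line, was measured on 12 expression arrays. The labels placed the arrays in 4 groups of 3: immunoprecipitates made with an antibody against TIAR, an RNA-binding protein encoded by TIAL1, or with a control IgG1 antibody, each from untreated cells and from cells exposed to short-wave ultraviolet light (UVC). The UVC dose and the time after exposure were not given in the sources used here. The labels call the 3 arrays of a group biological repeats and state no pairing of cultures across groups, so p-values measure the spread between these arrays.

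The deposited values are a score: each array's column of 9600 features had a mean of 0 and an SD of 1, as z scores have, with 2 decimals. No label or file header names the scanner, the background correction or the filter, and the quantity that was standardized and its log base were not given in the sources used here. The values were therefore used as deposited, and differences are given in z units, which are fractions of an array's own SD and not fold changes. The test had been planned for values on a log2 scale; the same linear model was used on the z scores. A z score sets each array's mean to the same level, so a feature's value is relative to the other features of its array, and a change in the total RNA recovered cannot be seen. No signal over background was available per array, and the number of arrays limits the precision.

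Features were named through the platform annotation. Of the 9600 features, 8496 carried 1 gene symbol, 21 carried several and 1083 carried none. Symbols were updated through the gene identifier with the RefSeq gene table of assembly GRCh38.p14 for 8493 features, and 3 kept the symbol of the annotation. The named features covered 6284 genes. Features with several symbols or none were tested and counted but not named. TIAL1 had 0 features with a symbol, so the targeted protein's own mRNA was not analysed here.

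A linear model with 4 group means was fitted to each feature with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, residual df 8, prior df 4.74), with all 12 arrays sharing 1 estimate of the spread per feature. The 6 contrasts were TIAR minus IgG1 in untreated cells, TIAR minus IgG1 after UVC, the mean of those differences, UVC minus untreated in the TIAR immunoprecipitate, UVC minus untreated in the IgG1 immunoprecipitate, and the interaction of antibody and UVC. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over the 9600 features of a contrast, with a threshold of 0.05. A difference is printed with its standard error from this model, and each group mean rests on 3 arrays.

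The comparisons, the gene lists, the rule for named genes and the other settings to be tried were fixed before the data were examined. Under the rule, each contrast named, among features with 1 symbol that passed the threshold and had a difference of the same sign for each of the 3 repeat numbers, the 10 highest and the 10 lowest, with 1 feature per gene. Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p were named as not past the threshold. MYC, EIF4A1, EIF4A2, EIF4E, EEF1B2, TIAL1, TIA1, ELAVL1, CDKN1A, GADD45A, GAPDH and ACTB were always read, and up to 4 members with the smallest p were read from each list. In these last cases a gene was represented by its feature with the highest mean over the 12 arrays, and list members that passed by another feature, looked up after the results were seen, are given as such.

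There were 22 gene lists, of which 600 of 935 genes were measured. Each was tested in each contrast with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 132 tests. The tests were repeated with an estimated correlation and with fry. Camera compares a list with all other genes, and fry tests whether the list's genes moved one way on balance, without such a comparison. For the antibody effect, the mean z score of each list per array was also compared by an exact 2-sided permutation of the antibody labels within each treatment (400 splits, smallest possible p 0.005), adjusted over the 22 lists. Within a single treatment, 3 arrays against 3 cannot give an exact p below 0.1. Correlations between contrasts run across features, which are not independent replicates, and carry no p. Shares of features have exact 95% binomial intervals, which cover counting error and treat features as independent.

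The model was tested on simulated data with the spread of the real arrays, in which 200 of 9600 features were shifted in the TIAR arrays. In the simulated contrast averaged over both treatments, 73% of shifts of 1 z unit and 99% of shifts of 2 were recovered with 5 false calls. In the simulated untreated contrast 29% and 90% were recovered with 9 false calls, and in the simulated UVC contrast 28% and 95% with 6. A simulated list of 16 genes shifted by 0.5 was called in 3 of 3 tests, with 0 false calls in 129 others. The simulated noise was independent between features and between arrays, and equal on all arrays. These figures therefore do not cover lists of correlated genes, arrays that are alike or arrays of unequal noise.

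The other settings tried were quantile normalization, centring of each array on its median, leaving out the dimmest 25% of features, an intensity trend with robust variances, a fit of only the groups compared, the repeat number as a block, array weights, 1 feature per gene, and leaving out each array in turn. After the data were seen, a fit was added in which IgG1 UVC arrays 1 and 2, which were unusually alike, were averaged and counted as 1 array. No array was left out of the reported values.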

Results

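TIAR is an RNA-binding protein that restrains the translation of mRNAs it binds, and the series asked which mRNAs associate with it in RKO colorectal carcinoma cells with and without UVC. RNA from immunoprecipitates made with an anti-TIAR antibody or with control IgG1 was hybridised to 12 arrays of 9600 features, 3 per antibody and treatment. Each array carried z scores with an SD of 1 and a median between -0.16 and -0.05, and a difference of 1 is 1 SD of an array.

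Across features, the 15 pairs of TIAR arrays correlated with a mean r of 0.843 (0.804 to 0.886) and the 36 pairs of a TIAR with an IgG1 array with a mean r of 0.736. Among IgG1 arrays, 14 of the pairs had a mean r of 0.700 (0.636 to 0.758). The remaining pair, IgG1 UVC arrays 1 and 2, had r = 0.910 (Spearman's rho 0.869). The SD of their difference was 0.42 z units, against 0.48 to 0.85 in the 65 other pairs of arrays and 0.70 or more in the other IgG1 pairs, and 164 features were identical. They were not identical arrays and were kept as 2 in the reported values. Counts with both averaged and counted as 1 array are given for TIAR minus IgG1, UVC with IgG1 and ribosomal proteins. For called members of the other lists it is said which still passed in that fit.

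**Figure D1:**
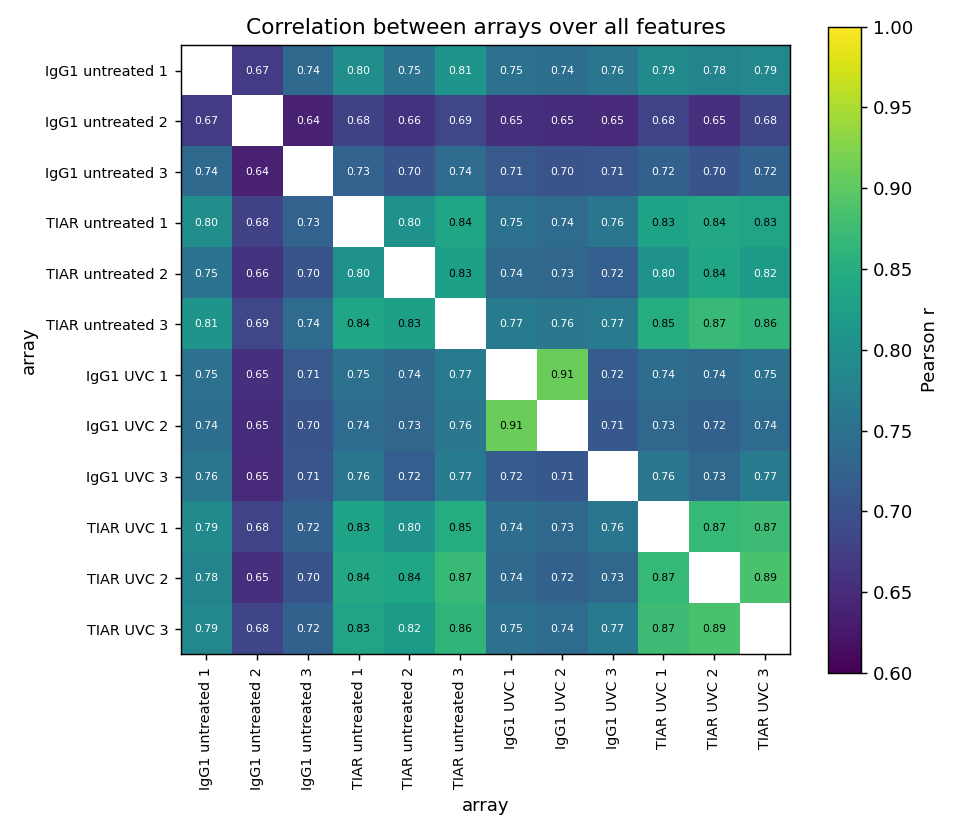
Pearson correlation across 9600 features between each pair of the 12 arrays, with rows and columns labelled by antibody, treatment and repeat. The pair of IgG1 UVC arrays 1 and 2 stands at 0.910, while the other IgG1 pairs lie between 0.636 and 0.758 and the TIAR pairs between 0.804 and 0.886.

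In untreated cells, 3 mRNAs were higher in the TIAR immunoprecipitate than in the IgG1 control. CSTB, which encodes cystatin B, an inhibitor of cysteine proteases, stood at 1.89 ± 0.36 (SD, n = 3) with TIAR and at -0.35 ± 0.50 with IgG1, a difference of 2.24 ± 0.28 (SE, adjusted p = 0.0168). ECPAS, which encodes a proteasome adaptor, was higher by 1.88 ± 0.24 (adjusted p = 0.0168). ABRAXAS2, which encodes the scaffold of a deubiquitinating complex, was higher by 1.76 ± 0.25 (adjusted p = 0.0275). These were the only features past the threshold in this contrast, with 0 lower, and 1151 of 9600 had an unadjusted p under 0.05 where 480 were due by chance. The next in line, not past the threshold, were CXXC5 at 1.64 (adjusted p = 0.0703) and COX10 at 1.17 (adjusted p = 0.0773), and in the other direction the ribosomal protein mRNA RPL7A at -1.30 (adjusted p = 0.0734), the keratin mRNA KRT8 at -1.70, RIN1 at -1.35, TOM1 at -1.23 and the ribosomal protein mRNA RPL31 at -1.01. With IgG1 UVC arrays 1 and 2 counted as 1, the same 3 features passed. Without TIAR untreated array 1, 2 or 3 the count was 0, and without IgG1 untreated array 1 or 2 it was 10 or 7.

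After UVC, 74 features were higher and 40 lower in the TIAR immunoprecipitate than in the control. CSTB and ABRAXAS2 led again, by 2.30 ± 0.27 and 2.15 ± 0.25 (adjusted p = 0.00467 for each). They were followed by CERT1, which encodes a ceramide transfer protein, at 2.09 ± 0.39, the metallothionein mRNA MT1H at 1.90 ± 0.38, CYRIB at 1.89, TMEM14B at 1.88 ± 0.29, RCAN1, which encodes a calcineurin inhibitor, at 1.82 ± 0.24, RYBP at 1.79, PCIF1, which encodes a methyltransferase of the mRNA cap, at 1.75 ± 0.26, and NOP10, which encodes a small nucleolar ribonucleoprotein, at 1.72. On the lower side stood SDHA, which encodes a subunit of succinate dehydrogenase, at -2.66 ± 0.56 (adjusted p = 0.0459), MAEA at -2.19, PLEKHO1 at -1.81 ± 0.22 (adjusted p = 0.00467) and TMEM160 at -1.81. The ribosomal protein mRNAs RPS19 at -1.71 ± 0.25 and RPS3A at -1.52 ± 0.23 (adjusted p = 0.0152 for each) were also lower, as were LRRC39 at -1.65, UFD1 at -1.56, ISL2 at -1.51 and SORBS3 at -1.45. Some of these differences went with a shift of the control. CERT1 stood at -0.37, -0.64 and -0.29 on the TIAR UVC arrays, and RCAN1 at 0.20, 0.36 and 0.01. On the IgG1 UVC arrays they stood at -1.68, -2.42 and -3.48, and at -1.85, -1.71 and -1.34. On the untreated IgG1 arrays they stood at -1.08, -0.34 and -0.37, and at -0.22, -0.90 and -0.41. TMEM160 rose in the control (means -2.67 untreated, -0.87 UVC) and fell with TIAR (-1.67, -2.68).

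Several of these genes had other features on the opposite side of 0 after UVC, none past the threshold: MAEA at 0.80, SDHA at 0.35, PCIF1 at -0.42, CYRIB at -0.32 and TMEM14B at -0.14, with another TMEM14B feature at 0.66. The calls after UVC covered 65 named genes higher and 25 lower, and 1756 features had an unadjusted p under 0.05. Centring each array on its median gave 66 higher and 20 lower in place of 74 and 40. With IgG1 UVC arrays 1 and 2 counted as 1, 9 of the features passed, 8 higher (CSTB with 2 features, ABRAXAS2, ECPAS, PCIF1, RCAN1, 1 of 2 features of CNBP, whose other stood at -0.04, and 1 of 2 of COX10, whose other stood at -0.75) and 1 lower (PLEKHO1). Counts with an array left out ran from 5, without TIAR UVC array 2 or 3, to 373, without IgG1 UVC array 3.

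The enrichment over IgG1 was measured on separate arrays in each treatment. Across features the difference in untreated cells and that after UVC correlated with r = 0.279 and rho = 0.278. Of the 74 features called higher after UVC, 58 were also above 0 in untreated cells (78.4%, exact 95% interval 67.3 to 87.1), where 51.2% of all features were. Of the 40 called lower, 29 were below 0 in untreated cells (72.5%, 56.1 to 85.4), where 48.7% of all features were. The 3 features called in untreated cells were all called after UVC.

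**Figure D2:**
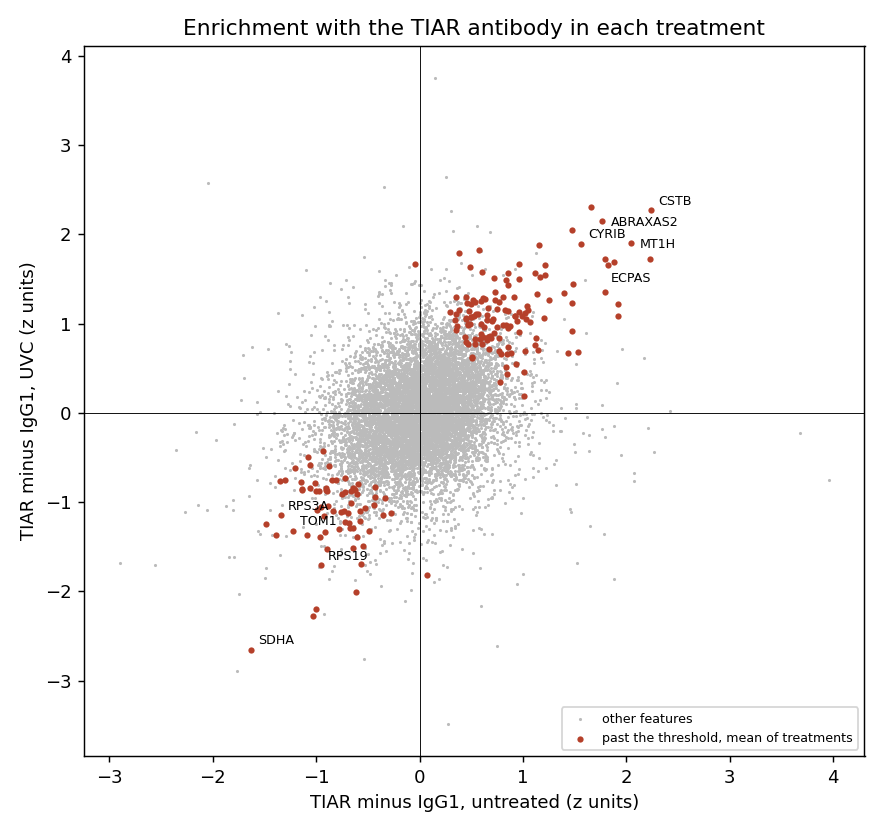
Difference between TIAR and IgG1 immunoprecipitates in untreated cells (horizontal axis, z units) and after UVC (vertical axis, z units) for 9600 features, with the 198 features past the threshold for the mean of both treatments in red. CSTB lies at 2.24 and 2.27 and SDHA at -1.63 and -2.66, and over all features r was 0.279.

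Averaged over both treatments, 128 features were higher and 70 lower in the TIAR immunoprecipitate, and this contrast of 6 arrays with 6 gave the most calls. CSTB was higher by 2.26 ± 0.19 (SE, adjusted p = 0.000278) and its other feature by 1.98 ± 0.19. ABRAXAS2 was higher by 1.96 ± 0.17 (adjusted p = 0.000278) and ECPAS by 1.79 ± 0.17 (adjusted p = 0.000393). The pancreatic amylase mRNA AMY2A was higher by 1.98 ± 0.38, the metallothionein mRNAs MT1H by 1.98 ± 0.27 and MT1X by 1.74 ± 0.30, CYRIB by 1.73 ± 0.21, the spliceosomal mRNA SNRPD3 by 1.57 ± 0.24 and DNAJC4 by 1.57 ± 0.35, with NOP10 also among the 10 highest. IgG1 untreated array 2 added to 2 of these differences, with AMY2A at -2.69 and DNAJC4 at -1.81. On the other IgG1 arrays AMY2A stood at -0.46 to -0.08 and DNAJC4 at -0.49 to 0.06. SDHA was lower by a difference of -2.14 ± 0.40 (adjusted p = 0.0197), although its other feature stood at 0.12 and did not pass. The 2 features also differed in level, with group means of 3.19 to 5.85 for the called one and -0.09 to 0.27 for the other. On each IgG1 UVC array the called feature was the highest of all features (5.30, 5.36 and 6.88). Whether both measure SDHA was not tested. RPS19 differed by -1.33 ± 0.18 (adjusted p = 0.00452), TOM1 by -1.27 ± 0.18, XKR8 by -1.37 and GPRC5A by -1.23, and MAEA, RPS3A, ISL2, RIN1 and MGC16275 completed the 10 lowest. The other MAEA feature stood at 0.23 and the other XKR8 feature at -0.03. RPS3A was the most heavily represented of these, with 8 of 8 features below 0 and 7 past the threshold. COX10 had 1 feature past the threshold in each direction, at 1.34 ± 0.14 and -0.80 ± 0.16, so no direction was read for that gene.

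These calls covered 113 named genes higher and 46 lower, with 1983 features at an unadjusted p under 0.05, and 78 of the 114 calls after UVC were among them in the same direction. With IgG1 UVC arrays 1 and 2 counted as 1, 44 features passed, 34 higher and 10 lower, all of which also passed with 12 arrays, and 11 of the 20 genes named here remained. Leaving out an array gave between 30 calls, without TIAR UVC array 2, and 352, without IgG1 UVC array 3.

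**Figure D3:**
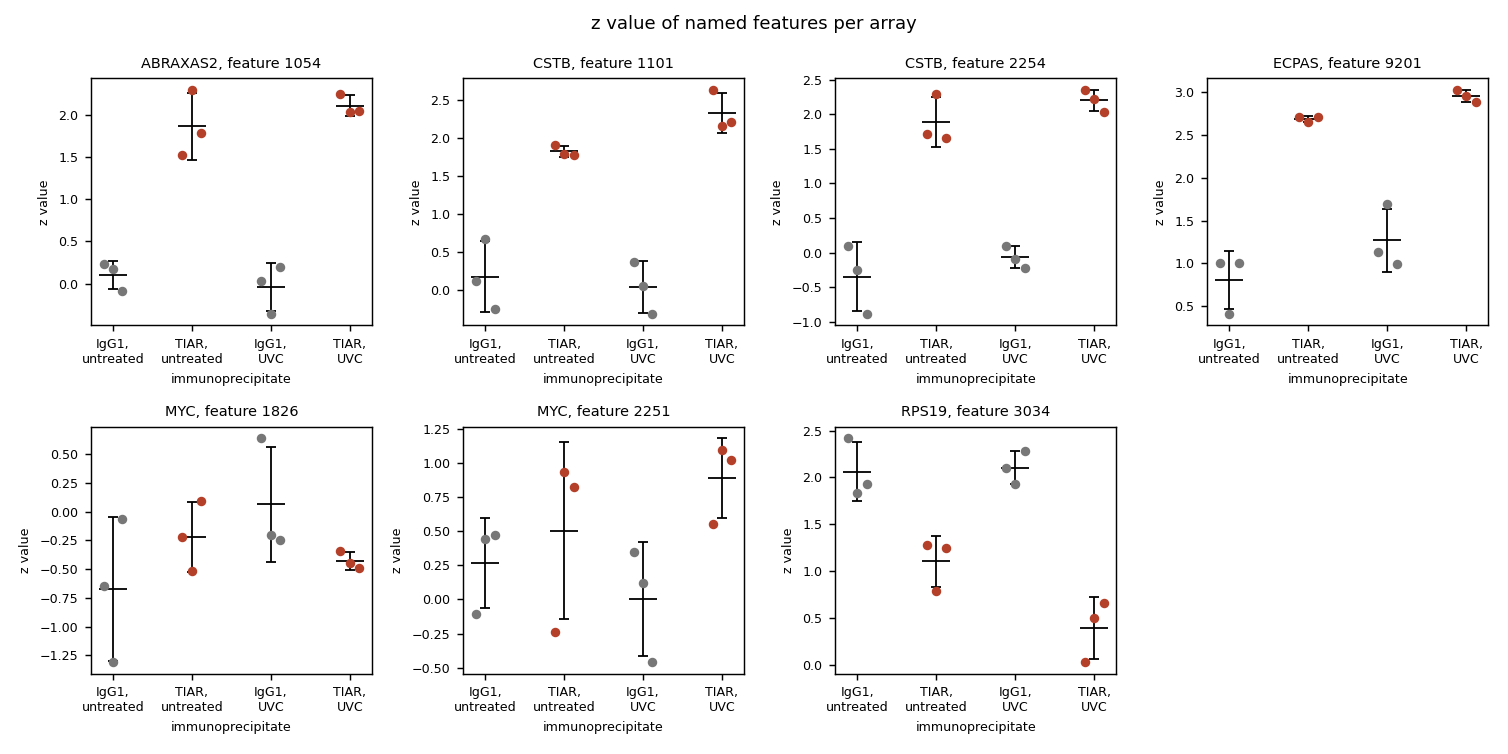
Value of named features on each array in z units, by antibody and treatment, with points for the 3 arrays of a group, a bar for the mean and whiskers for 1 SD. CSTB, ABRAXAS2 and ECPAS lie higher on every TIAR array than on any IgG1 array and RPS19 lower, with RPS19 at 1.11 and 0.40 on average with TIAR against 2.06 and 2.10 with IgG1, while the MYC features overlap between antibodies.

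Ribosomal protein mRNAs were the gene group that differed most between the immunoprecipitates by mean difference and by camera at the preset correlation. The exact permutation test and fry gave smaller p-values to other lists. They were lower with TIAR by a mean of -0.34 in untreated cells (camera adjusted p = 1.51e-07), -0.45 after UVC (adjusted p = 9.15e-09) and -0.39 averaged over both (adjusted p = 1.50e-11), with 52 of 58 measured genes below 0. With an estimated correlation, 0.207 for the averaged contrast, each of these calls ended (adjusted p = 0.770), and fry gave adjusted p-values of 0.140 in untreated cells, 0.0741 after UVC and 0.0421 averaged. Past the threshold over all features were 7 of the genes by the feature that represents each in the list, or 10 by any feature, all lower, among them RPS19, RPL7 at -0.96 ± 0.16 (of its 3 features 2 passed and the other stood at 0.44), RPL31 at -0.90 ± 0.16 and RPL41 at -0.74 ± 0.14, and adjusted over the list alone 15 were lower and 1 higher. Over all 148 ribosomal protein features 125 were below 0, or 120 after median centring. Of them 18 passed, or 15 after median centring, all lower, and the 18 were among the 70 lower calls. With IgG1 UVC arrays 1 and 2 counted as 1, 4 passed, among 10 lower calls. After UVC 0 passed in that fit, where 4 of the genes were lower by any feature with all 12 arrays. The list mean was 1.02 to 1.27 on the 6 TIAR arrays and 1.22 to 1.75 on the 6 IgG1 arrays (exact permutation p = 0.01, adjusted 0.0367), with IgG1 untreated array 2 at 1.22 inside the TIAR range.

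**Figure D4:**
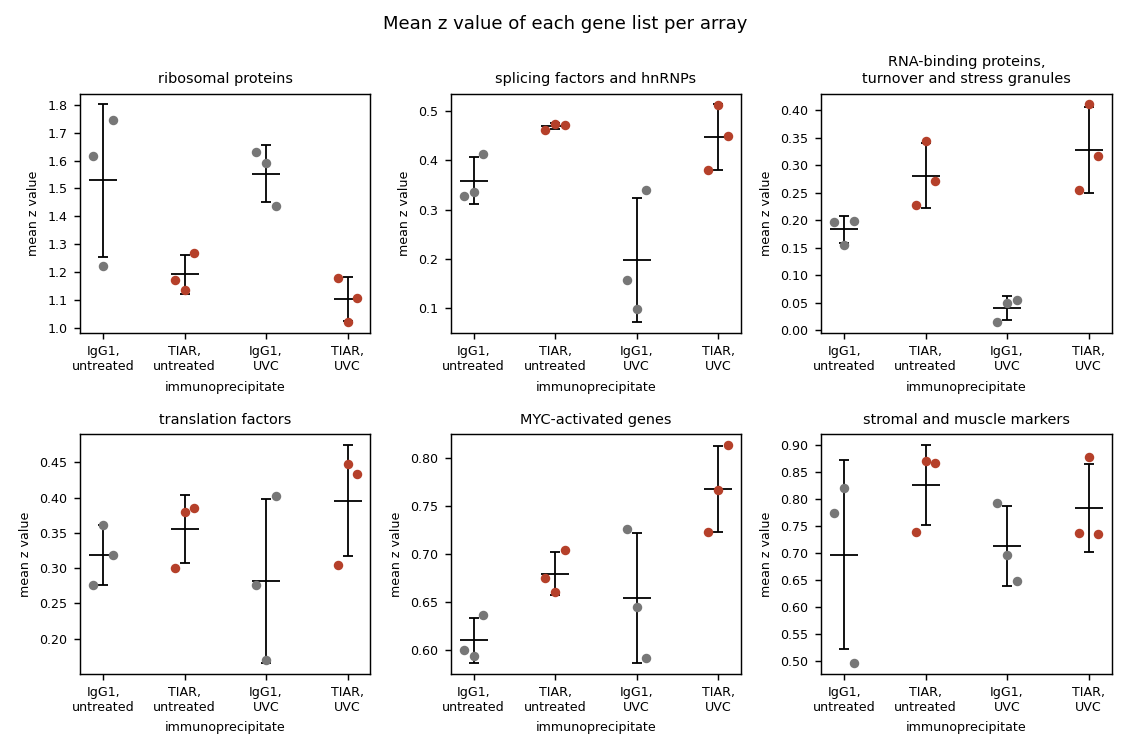
Mean z score of the measured genes of 6 lists on each array, by antibody and treatment, with points for the 3 arrays of a group, a bar for the mean and whiskers for 1 SD. Ribosomal protein mRNAs lie between 1.02 and 1.27 on TIAR arrays and between 1.22 and 1.75 on IgG1 arrays.

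Among mRNAs of the RNA-processing machinery, 27 of 35 genes for RNA-binding proteins of mRNA turnover and stress granules stood above 0 in the averaged contrast, with a mean of 0.19. The stress granule protein mRNA CAPRIN1 was the member past the threshold, at 0.73 ± 0.16, and adjusted over the list alone 4 were higher and 0 lower. Of 42 splicing factor and hnRNP genes, 30 stood above 0, with a mean of 0.18. SNRPD3 and SNRPF, at 1.44 ± 0.23, were higher, and adjusted over the list alone 2 were higher and 1 lower. SNRPD3 and SNRPF still passed with IgG1 UVC arrays 1 and 2 counted as 1, and CAPRIN1 did not. The list means of both groups differed between antibodies in the exact permutation test (p = 0.005, the smallest it can give, adjusted 0.0275), whereas camera did not call them (adjusted p = 0.282 and 0.414), nor did it with an estimated correlation (adjusted p = 0.770 for each). Fry called both lists averaged over treatments and after UVC (RNA-binding proteins adjusted p = 0.00581, splicing factors 0.0421, equal in each), and also the liver and gut-secretory (0.0398) and neural markers (0.0421) averaged. Liver and gut-secretory markers differed by 0.24 in the exact test, at the same exact permutation p, and neural markers by 0.18 (exact p = 0.025, adjusted 0.0786).

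Growth, cytoskeleton and mitochondrial groups held from 1 to 3 calls each by the feature that represents a gene in the list, and further calls by other features. Of 36 MYC-activated genes (mean 0.09, exact permutation p = 0.01, adjusted 0.0367), POLR1B, for a subunit of RNA polymerase I, was higher by 0.79 ± 0.15 and MCM7, for a replicative helicase subunit, by 0.73 ± 0.15, with its other feature at -0.20. By other features RAN at 1.21 ± 0.21 and NPM1 at 0.81 ± 0.16 passed too, and adjusted over the list alone 6 were higher and 3 lower. MCM7 was also the call among 37 cell cycle genes (mean 0.11), joined by MAD2L1 at 0.92 ± 0.19 through another feature, and of these genes 6 were higher and 3 lower adjusted over the list alone. Of 38 cytoskeleton genes (mean 0.10, exact permutation p = 0.005, adjusted 0.0275, fry adjusted p = 0.0421), TUBA1A was higher by 0.69 ± 0.15, and adjusted over the list alone 6 were higher and 1 lower. Other features of CFL1 at 0.86 ± 0.19 and TUBA1B at 1.00 ± 0.21 passed, while those representing these genes stood at -0.10 and -0.73. Of the features of TUBA1B 11 of 13 were above 0, and of CFL1 1 of 4. Liver and gut-secretory, neural and stromal markers had means of 0.24, 0.18 and 0.10 in the same contrast, beside the 0.09 and 0.10 of the MYC-activated and cytoskeleton lists. Among 55 oxidative phosphorylation genes (mean 0.01, median -0.02, camera direction up), SDHA and UQCRC2, at -0.81 ± 0.17, were lower and CYC1, at 0.56 ± 0.13, was higher, while the other UQCRC2 feature stood at 0.01 and those of CYC1 at -0.16 and 0.20, with 4 higher and 2 lower adjusted over the list alone. FKBP4 was higher by 0.74 ± 0.17 (other feature -0.24) among 35 heat shock and chaperone genes (mean -0.11), as was SEC61B by 0.98 ± 0.20 among 37 secretory pathway genes (mean 0.04), and adjusted over the list alone these lists held 1 higher and 0 lower, and 1 higher and 1 lower. By other features HSP90AB1 at 0.93 ± 0.21, P4HB at 0.81 ± 0.19 and ARF3 at 0.79 ± 0.15 passed, with other features as low as -0.03 for HSP90AB1 and -0.45 for ARF3. Of the members called in these lists, only SDHA and RAN still passed with IgG1 UVC arrays 1 and 2 counted as 1. Camera called none of these lists, with adjusted p-values from 0.690 to 0.963 at the preset correlation. With an estimated correlation camera's adjusted p-values ran from 0.770 to 0.967, with 0.874 for the MYC-activated and the cytoskeleton list.

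Groups tied to TIAR, stress and translation held few calls, and each of these came from 1 of several features of a gene. JUN, an immediate-early transcription factor mRNA, was lower by a difference of -0.90 ± 0.21 (adjusted p = 0.0489) among 24 immediate-early and AU-rich-element mRNAs (mean -0.02), with 1 higher and 2 lower adjusted over the list alone, although another JUN feature stood at 0.30. With limma, 0 members passed over all features in 8 further lists by the feature that represents each gene, given here with their mean difference and the number at an unadjusted p under 0.05. These were 44 translation factors (0.07, 9 genes), 7 mRNAs studied elsewhere as TIAR or TIA-1 targets (0.05, 1 gene), 19 mRNAs reported to bind HuR (0.13, 5 genes), 31 p53 and DNA damage genes (0.04, 6 genes), 14 histones (0.19, 1 gene), 35 proteasome and ubiquitin genes (0.10, 11 genes), 16 glycolysis genes (0.03, 4 genes) and 29 apoptosis genes (0.02, 2 genes). By another feature, EEF1G, an elongation factor mRNA, was lower at -0.82 ± 0.18, PSME3, for a proteasome activator, passed at 0.67 ± 0.14 in 1 of its 3 features, and NPM1 of the HuR list passed as above. CYCS, for cytochrome c, a member of the TIAR target, HuR, apoptosis and oxidative phosphorylation lists, passed at -0.77 ± 0.18 (adjusted p = 0.0451) in 1 of its 14 features, while another stood at 0.58 (adjusted p = 0.0720), so no direction was read for it. JUN, EEF1G, PSME3, NPM1 and CYCS did not pass with IgG1 UVC arrays 1 and 2 counted as 1. Camera's direction was down for glycolysis, whose median was -0.07, and down for apoptosis despite a positive mean and median. Adjusted over the list alone, the p53 list held 2 higher and 2 lower and the histones 1 higher and 0 lower, and the other 6 held 0. Camera gave these lists and the AU-rich-element list adjusted p-values from 0.810 to 0.963.

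Markers of other cell types were read beside these groups. Of 12 liver and gut-secretory markers (mean 0.24, exact permutation p = 0.005, adjusted 0.0275, camera adjusted p = 0.810), AMY2A was higher, and it was the member called when adjusted over the list alone. AMY2A did not pass over all features with IgG1 UVC arrays 1 and 2 counted as 1, and its value on IgG1 untreated array 2 was low, as given above. With limma, 0 members passed over all features among 14 blood markers (mean -0.03), 15 stromal and muscle markers (mean 0.10) and 15 neural markers (mean 0.18), and 0, 4 and 5 of them had an unadjusted p under 0.05. Adjusted over the list alone these lists held 0, 1 and 2 higher and 0 lower, and camera gave them adjusted p-values from 0.505 to 0.961.

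MYC, the mRNA named by the series, had 2 features that passed in no contrast. In untreated cells they differed between TIAR and IgG1 by 0.46 ± 0.33 and 0.24 ± 0.34, and after UVC by -0.49 ± 0.33 (adjusted p = 0.461) and 0.88 ± 0.34 (adjusted p = 0.197). The interaction of antibody and UVC was -0.95 ± 0.47 (adjusted p = 0.638) for the first and 0.65 ± 0.48 (adjusted p = 0.722) for the second, so that the features stood on opposite sides of 0. Of the other genes always read, TIA1, for a protein closely related to TIAR, stood at 0.62 ± 0.19 averaged over both treatments (adjusted p = 0.102) and ELAVL1 at 0.83 ± 0.27 after UVC (adjusted p = 0.140). EIF4A1 stood at 0.35 ± 0.25 in untreated cells and -0.47 ± 0.25 after UVC, its other feature at -0.69 ± 0.69 and 0.08 ± 0.69, and EIF4E at 0.10 ± 0.23 and -0.40 ± 0.23. ELAVL1 stood at -0.12 ± 0.27 in untreated cells, and EIF4A2, EEF1B2, CDKN1A, GADD45A, GAPDH and ACTB did not pass in any contrast either.

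Whether UVC altered the enrichment was asked by the interaction. It held 0 features past the threshold with limma, 751 at an unadjusted p under 0.05 and a smallest adjusted p of 0.144, and quantile normalization gave 1. Nearest to the threshold were PCIF1 at 2.28 ± 0.37 (adjusted p = 0.144), TMEM160 at -2.81 ± 0.45, PLEKHO1 at -1.89 ± 0.31, CXXC5 at -2.07 and LAD1, an epithelial basement membrane protein mRNA, at 4.62 ± 0.86. For the ribosomal protein list the interaction had a mean of -0.11 (camera adjusted p = 0.810). Calls made after UVC and missed in untreated cells were therefore not shown to differ between the treatments.

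Within the TIAR immunoprecipitate, no mRNA passed the threshold between UVC and untreated cells. PLEKHO1 came nearest at -1.57 ± 0.22 (adjusted p = 0.0647), followed by MEF2A at -1.90 ± 0.30 (adjusted p = 0.0816), NRGN at -2.26 ± 0.39 (adjusted p = 0.149), IFRD2 at -1.55 and MRGPRF at -1.27. On the higher side AP4S1 at 0.78, CETN3 at 0.99, CMSS1 at 0.98, the interleukin mRNA IL6 at 0.81 and CELA3A at 0.88 had the smallest p-values. Limma counted 0 features past the threshold, with 386 at an unadjusted p under 0.05 where 480 were due by chance, while array weights gave 2, and the trended variances or 1 feature per gene gave 1 each.

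In the IgG1 control, which measures the background, 2 named mRNAs and an unnamed feature were lower after UVC. PCIF1 differed by -2.21 ± 0.26 (adjusted p = 0.0121) and UBLCP1 by -1.75 ± 0.26 (adjusted p = 0.0441). PCIF1 fell in the control while it stood at -0.95 and -0.88 in the TIAR immunoprecipitate without and with UVC. DLST at -1.42, CNBP at -1.58 and LAD1 at -3.83 did not pass, nor did CXXC5 at 1.58, TMEM160 at 1.80, MCM2 at 1.11, TFB2M at 1.04 and FAXC at 1.67. There were 0 features higher, and 1242 had an unadjusted p under 0.05. With IgG1 UVC arrays 1 and 2 counted as 1, 1 feature passed, and without IgG1 UVC array 3, which leaves those 2 arrays alone in their group, 128 did. The count was 1 after quantile normalization, 47 with array weights, and 0 with the dimmest features left out, trended variances, only the groups compared or 1 feature per gene, and another split of the same 6 arrays gave 8. The UVC differences in the TIAR and IgG1 immunoprecipitates correlated across features with r = -0.0147 and rho = -0.0102.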

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

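The fit with the alike arrays counted as 1 was chosen after the data were seen, and the other settings before. The correlation of the enrichment between treatments (0.279) lay between 0.229 and 0.369 and 3 camera list tests at the preset correlation, all of ribosomal proteins, passed under every setting run for them. With an estimated correlation 0 of the 132 list tests passed, and fry kept 1 of those 3 (adjusted p = 0.140 in untreated cells, 0.0741 after UVC and 0.0421 averaged). Counts of features past the threshold moved more, and the cause was not tested. Array weights favoured the alike arrays. For TIAR minus IgG1 in untreated cells (3 as reported), the count was 11 with the dimmest features left out, 56 with trended variances, 0 with only the groups compared and 0 with array weights. After UVC (114), it was 336 with trended variances, 11 with only the groups compared, 2480 with array weights and 9 with the alike arrays counted as 1. Averaged over both treatments (198), it was 387 with the dimmest features left out, 644 with trended variances, 708 with array weights and 44 with the alike arrays counted as 1. For UVC minus untreated in the TIAR immunoprecipitate (0), it was 1 with trended variances, 2 with array weights and 1 with 1 feature per gene. In the IgG1 immunoprecipitate (3), it was 1 after quantile normalization, 47 with array weights, 1 with the alike arrays counted as 1, and 0 with the dimmest features left out, trended variances, only the groups compared or 1 feature per gene. For the interaction (0), it was 1 after quantile normalization. With the repeat number as a replicate block, the counts were 1 in untreated cells, 22 after UVC and 0 for UVC in the IgG1 immunoprecipitate, and it changed no other count by over 1.5 times. Over all features the numbers gave little sign of pairing. Deviations from the group means correlated at a mean of 0.0132 over 18 same-number pairs (-0.0489 to 0.0602). Over 36 pairs of different number the mean was -0.00664 (-0.0688 to 0.0607), and 7 of 12 arrays were closest to their own number. Pairing was not excluded for single genes. TIAR repeat 2 was the highest in both treatments for MT1X and NOP10, though not for CSTB or ABRAXAS2. The fit with the replicate block is therefore not set aside. Leaving out each array in turn gave 0 to 10 for untreated cells, 5 to 373 after UVC, 30 to 352 for the average, 0 to 2 for UVC in the TIAR immunoprecipitate, 1 to 128 in the IgG1 immunoprecipitate and 0 to 1 for the interaction. The count after UVC was 53, 24 and 19 without TIAR untreated arrays 1, 2 and 3, and 28, 5 and 5 without TIAR UVC arrays 1, 2 and 3. It was 43 and 204 without IgG1 untreated arrays 1 and 2, and 10, 9 and 373 without IgG1 UVC arrays 1, 2 and 3. For the average it was 113, 33 and 91 without TIAR untreated arrays 1, 2 and 3, 101, 30 and 32 without TIAR UVC arrays 1, 2 and 3, and 51, 50 and 352 without IgG1 UVC arrays 1, 2 and 3. Without IgG1 untreated array 2 the average gave 141 higher and 128 lower in place of 128 and 70. The 10 calls in untreated cells came without IgG1 untreated array 1, 7 without array 2, and 0 without any TIAR untreated array. In the IgG1 immunoprecipitate 128 came without IgG1 UVC array 3, and 1 without TIAR untreated array 3 or any TIAR UVC array. For UVC in the TIAR immunoprecipitate 2 came without IgG1 untreated array 1, and the interaction gave 1 without that array, TIAR untreated array 1 or IgG1 UVC array 3. Of 62 named calls none changed sign, and 55 passed after quantile normalization, 57 after median centring, 57 with trended variances, 59 with array weights, 42 with the replicate block, 22 with the alike arrays counted as 1, and 17 to 59 with an array left out. Of the 29 that could be fitted with only the groups compared 8 passed, of 48 bright enough to stay in 48 did with the dimmest features left out, and of 51 that represented their gene 50 did with 1 feature per gene. A second z scoring per array and an offset before the log were not run, since the values were z scores already. No signal over background was held, so what dim features limit was not measured beyond the filter above.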

Other observations

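The tests of the ribosomal protein list, of shared RNA content, of a shared RNA sample, of other features of called genes and of the sign in untreated cells were chosen after the results they bear on were seen, as were the families named next.

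Metallothionein mRNAs, whose proteins bind zinc and copper, were in part higher with TIAR. MT1H and MT1X passed the threshold averaged over both treatments, MT1G stood at 0.94 ± 0.32 (SE, limma adjusted p = 0.125) and MT2A at 0.61 ± 0.17 (limma adjusted p = 0.0786), and MT1E stood at -0.18 ± 0.17, with 4 of 5 features above 0 under each scaling. These genes are near-identical in sequence, and signal shared between them was not separated. MGST3, a microsomal glutathione transferase mRNA, was higher with 2 of 3 features past the threshold, the smaller at 1.34 ± 0.27, and the third at 0.18 ± 0.21. No MGST3 feature passed with IgG1 UVC arrays 1 and 2 counted as 1, where MT1H and MT1X did. Among mRNAs of translation elongation, EEF1A1 had 9 of 9 features below 0 (-0.57 to -0.16), none past the threshold, and EEF1G 8 of 8 with 1 past, or 7 of 8 after median centring. Of other elongation factors, EEF1B2 had features at -0.69 and -0.02, none past, and the feature representing EEF1D stood at 0.03. The translation factor list had a mean of 0.07. GAPDH had 4 of 4 features below 0 (-0.70 to -0.37), none past.

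IgG1 UVC arrays 1 and 2 were more alike than any other pair of arrays. A content common to UVC control immunoprecipitates stayed open, since its test rested on array 3 of the group alone, which correlated with them at 0.713 against 0.698 in the other IgG1 pairs and had the lowest array weight (0.317). Over features of middling signal the pair correlated at 0.674, against at most 0.348 in the other 65 pairs, so a single RNA sample or hybridisation may lie behind both arrays. For the hybridisation, differences between features of the same clone correlated at 0.531 in this pair and at up to 0.539 in another. The rule set beforehand counted a value within the range of the other pairs against a shared hybridisation. A margin for sampling error over the 132 clone pairs, not part of that rule, was wider than the gap between these values, so the question was left open. Counts, model p-values and exact permutation p-values that include this group carry the limit that its arrays may be fewer than 3 independent repeats.

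Ribosomal protein mRNAs were lower with TIAR. A trend with signal was argued against, as the list median of -0.43 lay below the lowest 2.5% (0.04) of 10000 random lists matched on signal. The signal-matched features of other genes had a mean of 0.15, so they did not fall with the list. That mean measures a shift and not noise, so a noise difference between the antibodies stayed open. A single array was argued against by the list mean of -0.34, its value nearest 0, without IgG1 untreated array 3. A property of mRNAs with a 5' terminal oligopyrimidine tract stayed open: 9 other measured mRNAs with such a tract had a mean of 0.0433 (exact permutation p = 0.16), while EEF1A1 and EEF1G, which carry it too, had prompted the test. More ribosomal protein mRNA in the IgG1 background, or less in TIAR complexes, cannot be told apart from 2 antibodies alone, and with an estimated correlation the list call ended (adjusted p = 0.770).

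Calls averaged over both treatments were not clearly borne out by other features of the same genes. Of 83 called genes with another feature, 50 differed in the same direction (60.2%, exact 95% interval 48.9 to 70.8), against 769 of 1405 genes without a call (54.7%, 52.1 to 57.4). Without ribosomal protein genes it was 41 of 74 (55.4%, 43.4 to 67.0). Noise of single spots may therefore account for part of these calls, and features that measure other transcripts or clones named wrongly were not tested. Called genes whose other features also passed, such as CSTB with 2 of 2 and RPS3A with 7 of 8, were exceptions. Even features annotated to the same clone correlated within an array at a mean of only 0.391 on TIAR arrays and 0.290 on IgG1 arrays. Gene names throughout rest on that annotation.

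Features of the same clone correlated within an array at 0.290 ± 0.0670 (SD, n = 6) on IgG1 arrays and at 0.391 ± 0.0261 on TIAR arrays, over 132 clone pairs. The difference of -0.101 (exact permutation p = 0.00216) lay just past the bound of 0.1 set for it beforehand, so more measurement noise on the IgG1 arrays may be part of their lower correlation with each other. Of the 114 features called after UVC, 87 had the same sign on the separate arrays of untreated cells (76.3%, exact 95% interval 67.4 to 83.8), which argues against sampling noise of the UVC arrays as the source of all of them.

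Other splits of the same arrays were counted. For the average over both treatments 1 of 100 splits, the real one, gave as many calls (198, highest other 2), a share under 0.05. The splits took IgG1 UVC arrays 1 and 2 as separate repeats. If both hold 1 RNA sample, these splits cannot exclude chance for the 198 calls. No splits were run with both counted as 1 array, where 44 features passed. For the interaction the real count was 0 (highest other 1), which every one of the 100 of 100 splits matches by construction, so the splits tested nothing there. With 3 arrays against 3, 10 splits are too few for a share under 0.05: TIAR minus IgG1 gave 3 in untreated cells (1 of 10, highest other 0) and 114 after UVC (1 of 10, highest other 1), and UVC minus untreated gave 3 with IgG1 (2 of 10, highest other 8). UVC minus untreated gave 0 with TIAR (highest other 1), which 10 of 10 match by construction.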
